A study of Drosophila melanogaster with 2 samples.

How the data were processed

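The series holds chromatin immunoprecipitation and sequencing (ChIP-seq) of a tagged transcription factor in whole embryos of Drosophila melanogaster, aged 8 to 24 h. The flies carried a transgene that encodes CG43689 fused to the green fluorescent protein eGFP, and chromatin was sheared by sonication to 200 to 800 bp and precipitated with an antibody against GFP, per the description in the labels. Another label field gives the antibody as CG43689, and the description was followed here. The 2 samples are biological replicates of 1 group, and no second condition was compared. No control or input library was analysed here, so no value below is set against a background measured without the tagged protein.

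The authors deposited peak lists on the dm6 assembly, not reads. Per the deposited file descriptions, 1 thresholded and 1 ranked list came from each replicate alone, and a main and a conservative thresholded list, each with its ranked list, came from both replicates together. Thresholding was by the irreproducible discovery rate (IDR), a measure of how consistently peaks rank between sets of calls. For a list from a single replicate, those sets cannot be the biological replicates. A thresholded peak was therefore not necessarily found in both replicates. The aligner, the peak caller and their versions are not given in the sources used here. Each peak carries the authors' signal value, whose scale differs between lists and which is used here only to describe, rank or filter peaks within a list, except for the descriptive correlation fixed beforehand. Each peak also has a deposited score of up to 1000; the lowest score in the main list was 830. A further column of the deposited lists holds a second score that falls below 0 for some peaks, and it was not used. The last columns of the ranked lists were not used, because no name ties them to a sample. The lists give no read counts, so the depth per library is unknown, and intervals on shares of peaks or genes cover counting error only.

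The main peak set was the pooled thresholded list that is not called conservative. Its background was the pooled ranked list that holds all of its peaks, without the peaks of the main list, and every alternative list was set against its own ranked list. Peaks on X, 2L, 2R, 3L, 3R and 4 were compared with the annotation of Ensembl 115, whose coordinates are those of dm6, and peaks on other contigs were left out of these comparisons. A promoter was taken as the DNA within 500 bp of any annotated transcription start site, and the remaining summits were put into classes in the order 5' UTR, coding, 3' UTR, other exon, intron and intergenic. Transposon and pseudogene models were left out. Positions are 1-based.

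Shares were compared with Fisher's exact test, two-sided. Replicate overlap was a shared base of 1 bp or more, tested by permutation against 1000 circular shifts of the replicate 1 peaks along each chromosome arm. Clustering was the share of peaks with another main summit within 10 kb, tested by permutation against 1000 draws from the ranked list. Symbols in the fixed gene lists that matched no protein-coding gene of the annotation (yellow, spalt, bagpipe, phm, Motif1BP, Caf1, calypso and Dl) were left out, some of them second names of members that were kept, such as M1BP. The 18 gene lists held protein-coding genes, and the background of each was the protein-coding genes with a ranked summit within 500 bp of a start site. The 24 motifs and the 2080 6-mers (each with its reverse complement) were searched within 50 bp of each summit and in a window of the same length centred 400 bp from the summit, on a side drawn at random, and compared with an exact McNemar test. The p-values were adjusted by the Benjamini-Hochberg method within each family (lists, motifs, 6-mers, feature classes, arms and gene biotypes), with a threshold of 0.05. The X share was also a test of its own, fixed without adjustment. These tests, lists and motifs were fixed before the data were examined. The genes named were the 25 protein-coding genes with a start site nearest to, and within 500 bp of, the strongest main summits with support in both replicate lists, together with CG43689 and up to 4 members of each list with the strongest summits. All p-values describe the placement of peaks in these lists, not variation between animals.

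The side of the start site on which summits lay, GC content and the comparison matched on GC were added after the data were seen. In that comparison each main summit was set against 5 ranked summits of the same promoter class and nearly the same GC content. The same ranked summit could be drawn for several main summits, and every draw was counted. The exact test treats the draws as independent, so the p-values of that comparison can be too small. Matching on promoter class alone drew summits in the same way.

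Alternatives were the list of each replicate alone, the conservative list, the main peaks found in both replicate lists, the main peaks at or above the median signal, start-site windows of 250 and 1000 bp, clustering within 5 and 50 kb, sequence windows reaching 25 and 100 bp from the summit, and other backgrounds. The procedures were tested on simulated data. Of the planted gene lists of 40 genes, 98.3% were recovered and 0% of the lists without an effect were called. The planted effect was strong, and most real lists had fewer members in the background, down to 13. This recovery therefore does not give the power for smaller lists or weaker effects. Of 20 planted 6-mers, 90% were recovered among the 2080 tested. Of simulated peaks kept within 50 bp of a replicate 1 peak, 100% were found as overlapping. That was certain in advance, because no replicate 1 peak was narrower than 73 bp. Of the simulated peaks placed elsewhere, 0.815% were found as overlapping. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9.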

Results

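CG43689 is an uncharacterized Drosophila gene whose product was profiled here as an eGFP fusion in whole embryos. The question the design answers is where in the genome the tagged protein was recovered, and how alike the 2 biological replicates were. The replicate 1 list held 1253 thresholded peaks out of 116767 ranked candidates, and the replicate 2 list held 1265 out of 121214. The main list, called on both replicates together, held 2088 peaks out of 151546 candidates, with a median width of 300 bp and a median signal of 88.1. Of these peaks, 2062 lay on the chromosome arms.

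The strongest promoter peaks lay at Ugalt, CG14100 and mRpL41. The strongest main peak (X, 2703745 to 2704023, dm6) had its summit 32 bp upstream of the start site of Ugalt (FBgn0024994), a UDP-galactose transporter gene. In the replicates' own lists the signal there was 503 and 540. The next named peak (3L, 19590490 to 19590736; signal 1036) had its summit 105 bp upstream of CG14100, and the one after it (2R, 15217630 to 15217873; signal 925) had it 147 bp upstream of mRpL41, a protein of the large mitochondrial ribosomal subunit. At PNPase, which encodes polynucleotide phosphorylase, the peak (3R, 31404542 to 31404760; signal 690) had its summit 80 bp downstream of the start site, in the 5' UTR. At Art3, an arginine methyltransferase gene, the peak (3R, 15229442 to 15229631; signal 633) was centred 126 bp upstream.

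The 25 genes named by signal were chosen for strong main peaks with a thresholded peak in both replicate lists, and their main signals were 443 or more. Their summits lay 9 to 214 bp from the nearest protein-coding start site, 18 of them upstream and 7 downstream. They include the Arf GTPase-activating protein gene CenG1A (signal 713), the translation and ribosome assembly factor gene eIF6 (604), the casein kinase gene gish (587), the chromodomain protein gene Chro (549), the prolyl isomerase gene Fkbp14 (541), the mitochondrial ribosomal protein gene mRpL23 (524) and the glutathione transferase gene GstE13 (523). Other named genes were CG7601 (726), CG5611 (672), Tcs5 (652), CG8320 (634), CG18549 (603), CG9147 (558), px (507), CG1888 (489), TRAM (484), Mnat9 (469), CG13390 (461), tank (444) and Tina-1 (443). Strong peaks also lay away from promoters. A peak of signal 970 (2L, 6612583 to 6612837) was in an intron 1030 bp from the nearest start site, that of CG11050, and a peak of signal 865 (2R, 13035223 to 13035449) was intergenic, 11917 bp from CG13323. Both were chosen after their values were seen.

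The replicates shared most of their thresholded peaks. Of the replicate 1 peaks, 880 of 1253 (70.2%) overlapped a replicate 2 peak, and 69.6% of the replicate 2 peaks overlapped one of replicate 1. Circular shifts gave 0.502% on average and 1.21% at most (permutation p = 0.001, one-sided, the smallest that 1000 shifts can give). Across the 880 pairs of overlapping peaks, which are not independent replicates, the signals had a Spearman rho of 0.768 (bootstrap 95% interval 0.736 to 0.802) and a Pearson r of 0.932. In the main list, 881 peaks overlapped a thresholded peak of both replicates, with a median signal of 140, 620 overlapped a peak of 1 replicate (81.0) and 587 of neither (63.6). The conservative list held 2048 peaks, and 85.3% of the main peaks overlapped one of them.

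**Figure D1:**
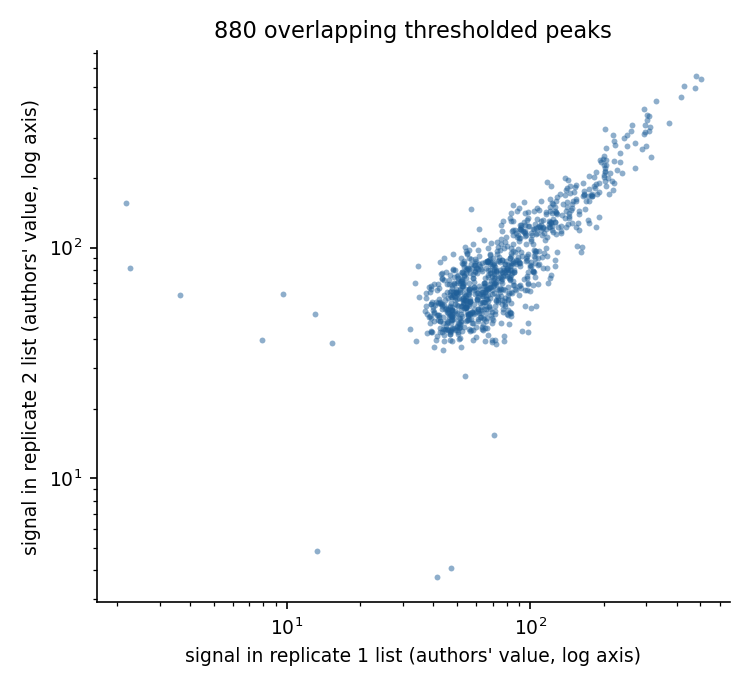
Signal of 880 overlapping thresholded peaks in the replicate 1 list (horizontal, log axis) and in the replicate 2 list (vertical, log axis), in the authors' units; each point is a pair of peaks. The points rise together, with a Spearman rho of 0.768, and a few pairs lie at a signal far below the rest in one list.

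Main peaks lay at promoters far more often than other candidate regions did. Of the 2062 summits, 952 (46.2%, Wilson 95% interval 44.0 to 48.3) were within 500 bp of a start site, against 12.7% of the ranked peaks not in the main list (odds ratio 5.89, Fisher's exact p = 1.53e-296). Coding sequence held 52 summits (2.52% against 18.4%, odds ratio 0.114, exact adjusted p = 9.84e-111), 3' UTRs 18 (0.873% against 2.59%, exact adjusted p = 5.79e-08), and intergenic DNA 253 (12.3% against 26.0%, exact adjusted p = 5.63e-52). Introns held 757 summits (36.7% against 38.6%, exact adjusted p = 0.0927), 5' UTRs outside promoters 9 (0.436% against 0.848%, exact adjusted p = 0.0540) and other exons 21 (1.02% against 0.801%, exact adjusted p = 0.263). Introns passed the test as depleted without replicate 1 (35.0%, exact adjusted p = 0.0246), without replicate 2 (33.5%, exact adjusted p = 0.00113), in peaks of both replicate lists (33.2%, exact adjusted p = 0.00132) and at or above the median signal (34.4%, exact adjusted p = 0.00815), and 5' UTRs did in the conservative list (0.395%, exact adjusted p = 0.0366). Against circular shifts of the same peaks, which placed 13.4% in promoters, the promoter share had a two-sided permutation p of 0.002, the smallest they can give. The side of the start site was examined after the data were seen. Of the promoter summits, 753 (79.1%) lay upstream of the nearest start site, against 40.6% of ranked promoter summits (odds ratio 5.53, Fisher's exact p = 1.90e-123). The median position of all 952 promoter summits, those downstream included, was 108 bp upstream.

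**Figure D2:**
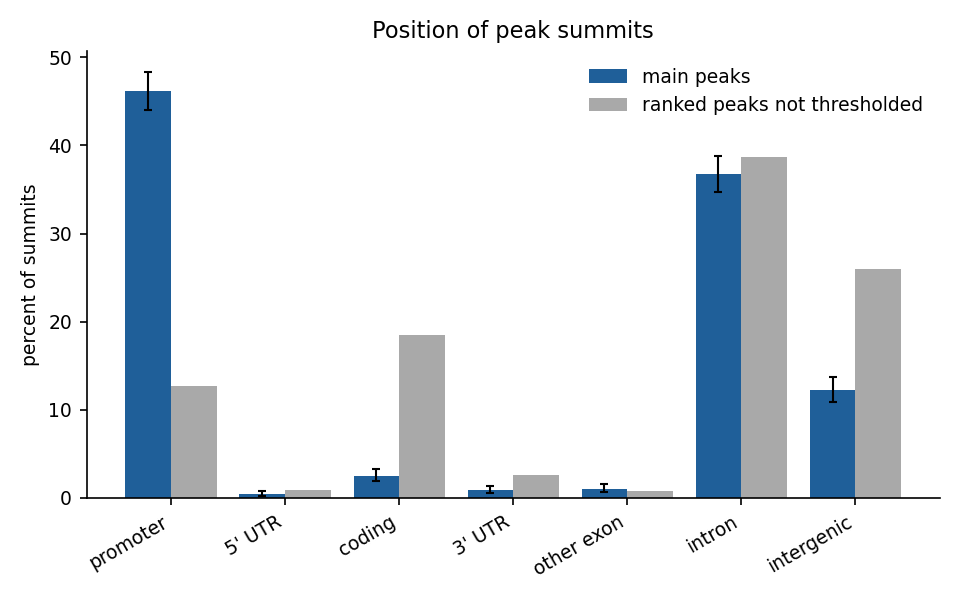
Share of summits (vertical, percent) in each class of annotation (horizontal), for the 2062 main peaks (blue, with Wilson 95% intervals) and for the ranked peaks not thresholded (grey). Promoters hold 46.2% of the main summits and 12.7% of the others, and coding sequence holds 2.52% and 18.4%.

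Genes with a peak at the promoter were often divergently paired. A main summit lay within 500 bp of a start site of 1166 protein-coding genes, and 730 of them (62.6%, Wilson 95% interval 59.8 to 65.3) had an opposite-strand protein-coding start site within 1000 bp upstream. Among genes with only a ranked summit this share was 31.8% (odds ratio 3.59, Fisher's exact p = 1.23e-90). One summit between 2 such genes counts for both, while the exact test treats genes as independent. Main promoter summits lay upstream more often than ranked ones (79.1% against 40.6%), so this double count can weigh more among them. The odds ratio can therefore be too high and the exact p too small.

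Ribosomal protein genes stood out among the 18 fixed lists. Of the 67 ribosomal protein genes in the background, 36 (53.7%, Wilson 95% interval 41.9 to 65.1) had a main summit at a start site, against 10.9% of other protein-coding genes (odds ratio 9.48, Fisher's exact adjusted p = 2.33e-16). The strongest were RpS27 (3R, 25247439 to 25247595; signal 284, summit 5 bp upstream), RpL23A (3L, 1668585 to 1668884; 209), RpL34b (204) and RpL32 (201). Genes for insulator and promoter-binding proteins had a peak at 6 of 15 (40%, interval 19.8 to 64.3; odds ratio 5.31, exact adjusted p = 0.0238), among them Chro, the insulator cofactor gene Cp190 (signal 168), Trl, which encodes the GAGA factor (167), and pzg (117). Genes for cuticle proteins and epidermal differentiation had a peak less often, at 1 of 88 (1.14%, interval 0.201 to 6.16; odds ratio 0.0905, exact adjusted p = 0.00490), the gene being Cpr51A (signal 61.2). The peaks of Cp190 and Cpr51A did not overlap thresholded peaks of both replicates. In the insulator list, Dref had the same peak as the ribosomal protein gene RpL13 (signal 104, summit 81 bp from Dref and 3 bp from RpL13). That peak counted for both lists, and whether the insulator call holds without it was not tested. With the replicate 2 list alone, the insulator list had an adjusted exact p of 0.0519 (33.3% against 8.26% of other genes, odds ratio 5.55) and the cuticle list 0.121 (1.30% against 8.36%, 0.144). With the main peaks found in both replicate lists both had 0.0598, the insulator list at 26.7% against 5.87% (odds ratio 5.83) and the cuticle list at 0% against 5.95%. The ribosomal protein list kept its call in those settings, at a lower share than in the main list. With the replicate 2 list alone it had 38.5% against 8.09% of other genes (odds ratio 7.10, adjusted exact p = 3.11e-10). With the main peaks found in both replicate lists it had 32.8% against 5.73% (odds ratio 8.05, adjusted exact p = 2.50e-10).

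The remaining 15 lists did not pass the exact test after adjustment. Among housekeeping groups, 2 of 20 proteasome genes (10%; Rpn3, signal 104, and Prosbeta2, 73.8), 6 of 48 respiratory chain genes (12.5%, led by ND-ASHI at 182) and 4 of 26 cell cycle and replication genes (15.4%, led by the E2F partner Dp at 126) had a peak. Heat shock and chaperone genes had a peak at 4 of 17 (23.5%), at Hsp27 (295), Hsp83 (146), Hsp26 (119) and Hsc70-5 (77.6). Polycomb and trithorax genes had one at 4 of 18 (22.2%), with ph-p (332), brm (316), E(z) (193) and Trl. Ecdysone pathway genes had one at 4 of 23 (17.4%), with the transporter gene E23 (317), Hr96 (143), tai (67.7) and Eip75B (59.0). The peaks of Prosbeta2, Hsc70-5, tai and Eip75B did not overlap thresholded peaks of both replicates.

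Tissue and patterning lists lay near or below the 11.2% of all protein-coding genes. Segmentation genes had a peak at 4 of 28 (14.3%; bowl, signal 210, nkd, 87.9, cnc, 74.6, and hry, 30.3), and homeobox patterning genes at 3 of 53 (5.66%; tin, 157, Dll, 110, and bcd, 95.2). The glial list had 2 of 13 (15.4%), the blood-brain barrier receptor gene moody (337) and Gli (81.6). Neuronal genes had 3 of 36 (8.33%), the pan-neuronal RNA-binding protein gene elav (243), Nrx-1 (114) and dlg1, and muscle genes 3 of 36 (8.33%), Msp300 (237), tin and the titin-like gene sls (129). Proneural and neuroblast genes had 1 of 26 (3.85%, numb, 174), gut, fat body and hemocyte genes 1 of 24 (4.17%, fkh, 87.6), signalling genes 2 of 32 (6.25%, spi, 105, and Krn, 61.9) and tracheal genes 0 of 14 (interval 0 to 21.5%). The peaks of nkd, cnc, hry, tin, bcd, Gli, dlg1 and Krn did not overlap thresholded peaks of both replicates.

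**Figure D3:**
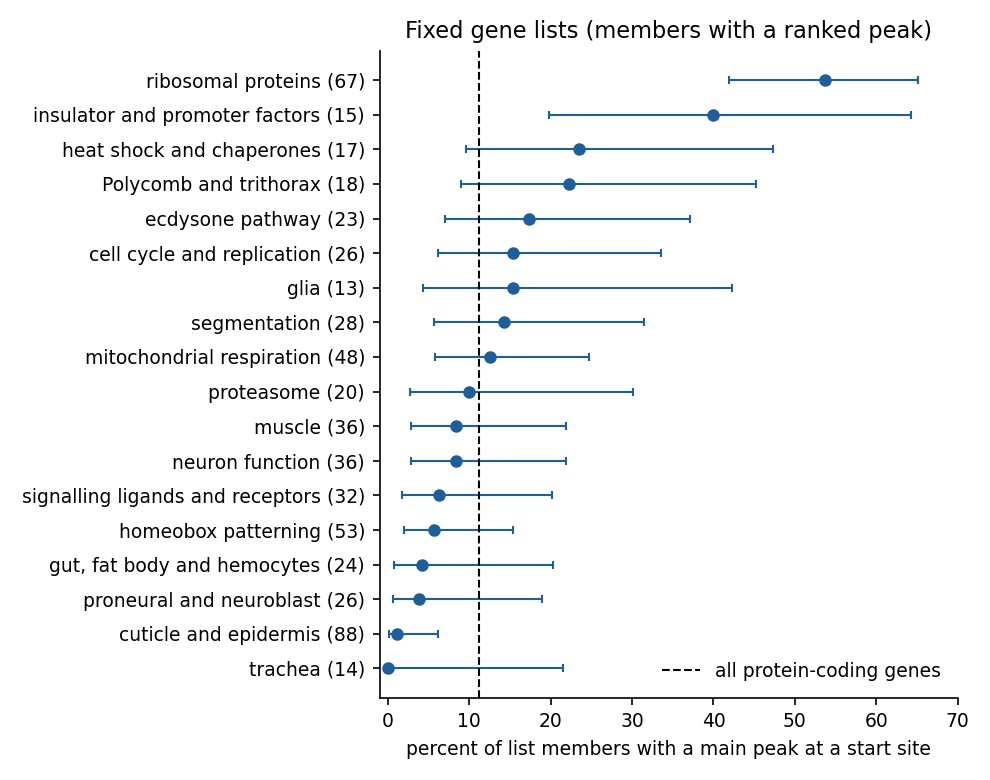
Share of each fixed list's members (horizontal, percent) with a main summit within 500 bp of a start site, with Wilson 95% intervals; the number of members in the background stands in parentheses. The dashed line is the share among all protein-coding genes, and the ribosomal protein list at 53.7% lies farthest above it.

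Genes for long noncoding RNAs, microRNAs, snoRNAs and tRNAs had a promoter peak less often than the 11.2% of protein-coding genes. Long noncoding RNA genes had one at 83 of 1951 (4.25%, exact adjusted p = 1.36e-23), microRNA genes at 6 of 196 (3.06%, exact adjusted p = 1.42e-04), snoRNA genes at 7 of 143 (4.90%, exact adjusted p = 0.0226) and tRNA genes at 3 (1.96%, exact adjusted p = 1.18e-04; tRNA:Tyr-GTA-1-8, tRNA:Leu-TAA-2-1 and tRNA:Phe-GAA-1-2). No main summit lay at the 22 snRNA genes (interval 0 to 14.9%, exact adjusted p = 0.197) or the 5 rRNA genes in the background (exact adjusted p = 1). With all annotated genes as background, 0 of 99 rRNA genes had one, which passed the test (exact adjusted p = 4.04e-04). Only 5 of the 99 had any ranked summit at a start site, and the others could not have a main one. That call therefore does not show depletion. The snRNA share was 10.5% against 8.65% of coding genes in the replicate 1 list (exact adjusted p = 0.813). The snoRNA call (odds ratio 0.409) was lost without replicate 1 (6.78% against 8.30% of coding genes, odds ratio 0.804, exact adjusted p = 0.883) and in peaks of both replicate lists (3.50% against 5.90%, 0.578, p = 0.424). At or above the median signal it missed the threshold at an odds ratio of 0.385 (2.80% against 6.96%, exact adjusted p = 0.0696), and with a start-site window of 1000 bp the direction turned (14.3% against 11.8%, 1.25, exact adjusted p = 0.367). A summit near a noncoding gene can also lie at a neighbouring promoter, which these counts do not separate.

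No arm passed the adjusted test in the main list, and no main peak lay on chromosome 4. The largest gap was on 3R, with 23.2% of main and 25.5% of ranked peaks (odds ratio 0.882, Fisher's exact p = 0.0167, adjusted 0.10). The X held 376 of 2062 peaks (18.2%, Wilson 95% interval 16.6 to 20), against 17.1% of the ranked peaks (odds ratio 1.08, Fisher's exact p = 0.185, adjusted 0.278). The 26 main peaks left out for lying off the arms were all on unplaced contigs assigned to the X, and this share does not count them. Ranked peaks off the arms were left out as well. Chromosome 4 held 0 main peaks (interval 0 to 0.186%) and 0.128% of the ranked ones (exact p = 0.121). It makes up 1.01% of the length of the arms, so ranked peaks were themselves sparse there and the test had little to compare. The X share passed after adjustment over the arms in the replicate 2 list (19.9%, exact p = 7.73e-04, adjusted 0.00464) and in peaks of both replicate lists (20.3%, exact p = 0.0151, adjusted 0.0454). It passed only before adjustment in the replicate 1 list (18.8%, exact p = 0.0207, adjusted 0.0620) and in peaks at or above the median signal (19.7%, exact p = 0.0281, adjusted 0.0844), and not in the conservative list (18.1% against 17.3%, exact p = 0.300). Main peaks also clustered. Of them 52.8% had another main summit within 10 kb, against 28.8% in draws from the ranked list (permutation p = 0.001, the smallest they can give).

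The DNA under the summits was AT-rich. GC content, examined after the data were seen, was 35.0% ± 10.7 (SD, n = 2062 peaks) within 50 bp of main summits and 43.5% ± 7.66 (SD) in windows of that length 400 bp to both sides, and it was lower than there at 1521 peaks and higher at 518 (exact sign test p = 7.06e-114). Ranked peaks not in the main list had 46.0% at their summits. The content fell with signal, from 41.6% in the 412 main peaks with the lowest signal to 30.8% in the 413 with the highest. Among the latter it was 32.0% outside promoters. At Ugalt the 41 bases around the summit (X, 2703864 to 2703904) read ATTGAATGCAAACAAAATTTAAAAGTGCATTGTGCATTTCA on the forward strand, of which 30 are A or T. In the intron near CG11050 the 41 bases (2L, 6612697 to 6612737) read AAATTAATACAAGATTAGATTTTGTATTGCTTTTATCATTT, with 34 A or T.

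**Figure D4:**
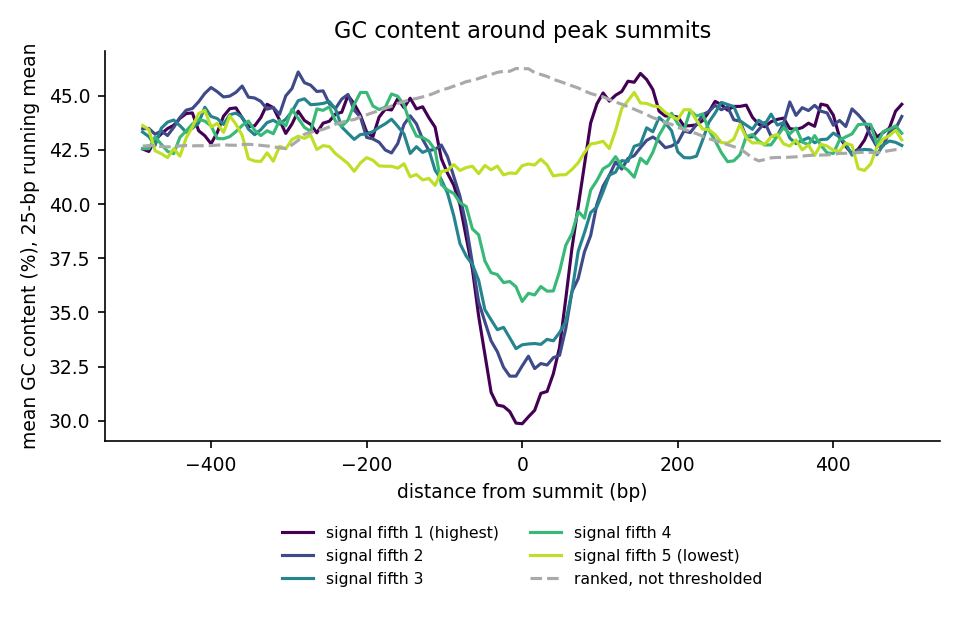
Mean GC content (vertical, percent, running mean over 25 bp) against distance from the summit (horizontal, bp), for main peaks in 5 groups by signal (solid lines) and for ranked peaks not thresholded (dashed). The dip at the summit is deepest in the group with the highest signal, where the mean within 50 bp is 30.8%, and is nearly absent in the lowest group at 41.6%.

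Motifs made of A and T were more frequent at summits than in the peaks' own flanks. Of 2080 6-mers, 290 were enriched at summits and 560 depleted (exact McNemar tests, adjusted), and all 36 that hold only A and T were among the enriched. The strongest was AAATAT, at 32.7% of summits and 15.7% of flanks (exact adjusted p = 1.29e-32). Of the 24 fixed motifs, 7 were enriched and 3 depleted. TATA box matches lay at 7.95% of summits and 3.35% of flanks (exact adjusted p = 2.40e-09), Mef2 matches at 6.64% and 3.01% (3.33e-07), GATA matches at 21.6% and 16.2% (4.40e-05) and homeodomain matches at 9.60% and 6.11% (2.07e-04). CTCF matches lay at 1.26% and 0.291% (exact adjusted p = 0.00214), the DNA replication-related element DRE at 1.12% and 0.388% (0.0285) and Su(Hw) sites at 0.679% and 0.145% (0.0305). CA repeats lay at 0.921% of summits and 4.27% of flanks (exact adjusted p = 2.04e-10), GAGA matches at 3.44% and 5.67% (0.00223) and Sp or Klf matches at 0.630% and 1.70% (0.00626). Against ranked summits matched on promoter class and GC, added after the data were seen, CTCF alone of the 24 passed the exact test (1.26% against 0.126%, adjusted p = 1.06e-10), and 39 6-mers were enriched and 29 depleted. In that comparison TATA (7.87% against 8.76%), Mef2 (6.61% against 6.78%), homeodomain (9.57% against 11.3%) and GAGA matches (3.45% against 2.87%) turned direction, none past the test. The GAGA depletion was also lost against summits matched on promoter class alone (3.44% against 3.48%, exact adjusted p = 1) and in the wider window (exact adjusted p = 0.786). For Sp or Klf only the call was lost, and matches stayed rarer at summits than in flanks. This held in the replicate 2 list (0.402% against 1.21%, exact adjusted p = 0.0903) and in peaks of both replicate lists (0.456% against 1.48%, 0.147). It also held in the narrower window (0.339% against 0.727%, exact adjusted p = 0.292). In the lists of each replicate alone and in the peaks at or above the median signal, CTCF, DRE and Su(Hw) missed the threshold, with adjusted exact p from 0.0638 to 0.905.

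The tagged gene itself had no peak. CG43689 (FBgn0263772; X, 4075743 to 4092237, forward strand) had 0 thresholded peaks within the gene and 5 kb to each side in the main, the conservative and both replicate lists. Among the ranked candidates of the pooled list, 37 lay in that window, the strongest at 4071888 with a signal of 52.0, which is rank 3199 of 151546.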

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

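The test of constitutively active genes and the test of low-signal peaks were chosen only after results that bear on them were seen, and the test at a fixed distance from the start site was set before its own value but after the promoter ratio was known.

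Signal lay outside the chromosome arms and outside the thresholded list. In the main list, 26 peaks lay on 25 unplaced contigs assigned to the X, which the comparisons did not use; their highest signal was 303, and 4 had a thresholded peak in both replicate lists. A further 88 ranked peaks scored at least as high as the weakest main peak but were missing from the main list, 72 of them on the arms. The deposited file descriptions name a further input file for the thresholded lists that was not available here, and whether it removed these peaks was not tested. The strongest, chosen after their values were seen, lay in an intron on 2L (480971 to 481208, signal 948, 1404 bp from a start site of cbt), in an intron near Lk6 (3R, 11760946 to 11761160, signal 745) and in the promoter of CG18428 (3R, 24109085 to 24109312, signal 452).

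Strong peaks sat on AT-rich DNA. The tests below counted all main summits, whatever their signal. They concern where main peaks lay, and not the fall of GC content with signal. Divided into tiles of 100 bp, the arms argue against composition alone: among tiles of 30% GC or less, the share with a main summit was 7.0 times as high in promoters than elsewhere (95% interval 6.05 to 8.09). They also argue against promoter location alone, since within promoters that share was 4.45 times as high at 30% GC or less than at 40 to 50% (3.76 to 5.26), and against distance to the start site alone, since 50 to 200 bp upstream the ratio was 3.30 (2.54 to 4.29). Open DNA that is also AT-rich, and a library bias acting on open DNA, stay open, because neither accessibility nor a control library was analysed here. The design has 1 group, so no biological explanation was tested.

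Ribosomal protein promoters had peaks more often than others. AT-rich promoters do not account for all of it, since with genes stratified by the lowest GC of any promoter window the odds ratio was 7.96 (95% interval 4.92 to 12.9), against 9.48 without strata, and the median lowest GC was 21.8% in ribosomal and other genes alike. The proteasome and respiration lists together gave 8 of 68 genes and an odds ratio of 1.06 (0.543 to 2.29), below the interval of the ribosomal list (5.85 to 15.3). These lists were therefore not bound like the ribosomal one. Their members were chosen by gene name, and which of them were active was not known. The comparison thus cannot decide whether all constitutively active promoters were bound alike. Recovery that follows the very high transcription of ribosomal protein genes stays open, because no expression data were analysed here.

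Some main peaks had a signal below 18.6, the median of the candidate list, although their scores passed. All 54 of these (100%, Wilson 95% interval 93.4 to 100) overlapped a stronger ranked peak of passing score, against 6 of the 2034 other main peaks, and 48 shared the exact score of such a neighbour. Only a neighbour with a higher signal counted, which favours peaks picked for a low signal. The contrast with the other main peaks was therefore partly set in advance. Overlap with a shared score is what peaks that take over the score of a stronger neighbour would show, so these 54 may be shoulders and not separate sites. No biological explanation was tested.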

How the results depend on the processing

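Settings other than those named as added were fixed before the data were examined. No setting turned or ended the call on replicate overlap, promoter, upstream or divergent share, clustering or summit GC content, and the number of feature classes and of noncoding biotypes past the threshold moved by at most 1.5 times, while the peaks and genes counted within them moved more. The X chromosome share passed its own exact test without replicate 1 (19.9%), without replicate 2 (18.8%), in peaks found in both replicate lists (20.3%) and at or above the median signal (19.7%), and only the sets of 19.9% and 20.3% passed once adjusted over the arms. The rank correlation was 0.679 over all ranked peaks near main summits. Called gene lists numbered 1 without replicate 1, 3 without replicate 2 and 1 for peaks in both lists. Insulator and promoter factors had peaks at 33.3%, 35.7% and 26.7% in these sets, and cuticle and epidermis at 1.30%, 0% and 0%. Without replicate 1 and without replicate 2, DRE (1.05% of summits against 0.241% of flanks, and 1.37% against 0.644%), CTCF (1.29% against 0.402% in each) and Su(Hw) (0.482% against 0.322%, and 0.724% against 0.322%) lost their call in both. In the first only, Sp/KLF lost its call (0.402% against 1.21%, and 0.322% against 1.29%) and E-box CAGGTG gained one (2.09% against 4.34%, and 2.33% against 3.94%). These lists hold fewer peaks, which alone weakens a test. In the conservative list DRE (0.989%) and Su(Hw) (0.692%) lost their call. In peaks of both lists DRE (1.14%), Su(Hw) (0.342%) and Sp/KLF (0.456%) lost theirs. Above the median signal DRE (1.16%), CTCF (1.16%) and Su(Hw) (0.677%) did, and E-box CAGGTG gained a call as depleted (2.3% of summits against 4.55% of flanks). The narrower window ended the call for DRE (0.630% against 0.339%) and Sp/KLF (0.339% against 0.727%), with 253 6-mers depleted. The wider ended it for GAGA (10.8% against 11.3%) and gave one to Ohler motif 7 (4.46% against 2.18%). Against ranked summits matched on promoter class, GAGA (3.44%) and Su(Hw) (0.679%) lost their call, Ohler motif 1 (0.388%), E-box CACGTG (0.582%) and E-box CAGGTG (3.49%) gained one, and 447 6-mers were enriched and 936 depleted. Matched also on GC, an added setting, 1 fixed motif was called, with 39 6-mers enriched and 29 depleted. DRE (1.12%), Su(Hw) (0.680%), GATA (21.6%), CA repeat (0.923%) and Sp/KLF (0.631%) lost their call there, and GAGA (3.45%), TATA (7.87%), homeodomain (9.57%) and Mef2 (6.61%) turned direction without passing the test. That matching removes composition by construction, and for the other changes the cause was not tested. Of 432 values for peaks at named genes, 69 lay beyond 500 bp of the start site. No paired analysis was possible because the samples form 1 group. The unknown read depth limits what a missing peak can show.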

Other observations

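All tests in this part were chosen after the main results were seen, and their p-values are adjusted over 5 added gene lists or, for 6-mers, over all 6-mers. Genes for mitochondrial ribosomal proteins had a main summit at 10 of 44 start-site sets (22.7%, Wilson 95% interval 12.8 to 37.0; odds ratio 2.35, exact adjusted p = 0.0661), with mRpL41 (signal 925), mRpS23 (713), mRpS10 (633) and mRpL23 (524) at the head. The peak of mRpS23 is the one nearest to CenG1A, and that of mRpS10 the one nearest to Art3. Translation initiation factors had 5 of 33 (15.2%, exact adjusted p = 0.509; eIF6, eIF1, eIF5B, eIF3h and eIF3c) and aminoacyl tRNA synthetases 4 of 23 (17.4%, exact adjusted p = 0.509; GluProRS, IleRS, SerRS and ThrRS). Histone genes had 1 of 6 (His2Av, 140; exact adjusted p = 0.509). Odorant and gustatory receptor genes, which act in sensory neurons, had 0 of 99 (interval 0 to 3.74%, exact adjusted p = 7.40e-05).

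With promoter class and GC matched, a few 6-mers still marked the main summits. Ranked summits could be drawn repeatedly for that comparison, so its p-values can be too small. ACAGTG lay at 7.33% of them and 3.42% of the matched ranked summits (exact adjusted p = 7.85e-11), AGTGTA at 7.58% and 4.66% (6.33e-05), CTGTGC at 5.78% and 3.27% (6.33e-05) and TGTGCA at 8.26% and 5.91% (0.00750). GCGCCA, which overlaps the fixed CTCF motif, lay at 4.08% and 2.42% (exact adjusted p = 0.00496), and of the 36 6-mers of A and T alone only ATATTA stayed enriched (20.8% and 17.2%, exact adjusted p = 0.00716).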
